A study of Homo sapiens with 12 samples.

How the data were processed

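RNA sequencing was analysed for 12 libraries of human cell lines, 3 each of A549 and MDA-MB-231 in 2D culture and in Matrigel. Per the labels, cells in 2D were grown in DMEM with 10% FBS to about 80% confluence and cells in 3D for 4 days, total RNA was extracted with TRIZOL, and libraries were made with a stranded total RNA kit that removes ribosomal RNA. The deposited tables hold RSEM gene results, per the submitters' processing notes, which name the human genome build hg19. The RSEM version, the aligner, the annotation release and the strand setting are not given in the sources used here. Expected counts are estimates that split reads shared between genes, as deposited per gene for 27968 gene symbols in each library. TPM values were also deposited beside the expected counts and are scaled to transcript length and library total. No coordinates are given because the reference at hand is of another build. The number of columns of other series was 0.

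Expected counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr, which left 15304, and libraries were scaled with TMM, with factors from 0.809 to 1.129. One model with 4 group means was fitted to all 12 libraries with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), so that all groups share the estimate of spread. The comparisons were 3D against 2D in each line, the difference between those changes (A549 minus MDA-MB-231), and A549 against MDA-MB-231 in each culture. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. A gene counted as changed the same way in both lines if it passed in both with the same sign. Tests are two-sided.

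A total of 40 gene lists with 1092 members was fixed before the data were examined, of which 1077 members were found by symbol. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over the 38 lists tested. Erythroid markers and genes encoded by mitochondrial DNA had too few tested genes. Camera was repeated with an estimated correlation, and fry tested whether the genes of a list moved one way. A gene counted as risen or fallen in a list only if its own edgeR test passed.

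Named genes followed a rule set before the data were examined. For each line the 6 largest rises and 6 largest falls were taken among genes that passed, with an average log2 CPM of at least 3 and libraries of the 2 cultures that did not overlap. The difference between lines gave 5 genes per direction, the shared changes 5 per direction and the lines in 2D 4 per direction. Each list described gave up to 4 members with the smallest p. Genes of snoRNA, snRNA, miRNA, ribosomal RNA, 7SK, 7SL and Y RNA and symbols that are only a LOC number were left out of the rule, but other structural RNA genes, such as TERC and RPPH1, were not. Antisense genes, pseudogenes, HLA-DRB1 and HLA-DQB1 are reported as uncertain. Other named genes were not checked for close copies, so the lack of this mark does not mean that they share no reads.

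Total expected counts ranged from 5609327 to 28171901 per library. A group at 0 counts was set to a floor of 3 counts over its 3 libraries, and the fold is then a lower bound. Ratios against 1 to 3 counts carry an exact 95% interval. Intervals and floors cover counting error only, since PCR copies are not independent molecules. Mean fragment length was taken from the difference between length and effective length of genes of at least 2000 bases. Single values per library were compared with exact permutation tests, for which 3 against 3 libraries allow p = 0.1 at the smallest. A gene at 0 in every library of a line has no testable difference between lines in its 3D change.

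The test was checked on simulated counts for 15304 genes with 200 changed genes. All simulated groups shared 1 spread per gene. In the real data the biological coefficient of variation was 0.180 in A549 3D against 0.0376 to 0.0563 in the other groups. The simulation leaves out this unequal spread and the far larger number of genes called, so its shares need not hold for the real libraries. For A549, 57.1% of genes with a log2 fold change of 0.5 were recovered, 84.4% with 1 and 90.4% with 2, and 2.5% of calls were false. For MDA-MB-231 the shares were 52.4%, 77.9% and 92.8%, with 2.6% false. For the difference between lines they were 11.9%, 74.7% and 83.3%, with 4.8% false. For the lines in 2D they were 49.2%, 88.5% and 95.2%, with 5.4% false, and in 3D 40%, 82% and 86.4%, with 5.7% false. In simulated A549 libraries camera called the 1 moved list and 0 of 37 others, but simulated genes vary independently, unlike real ones.

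Alternatives set before the data were examined were RLE and upper-quartile scaling, DESeq2 (1.42.0), no filter, a filter at CPM of at least 1 in at least 3 libraries, limma on log2(TPM + 1), 6 libraries fitted alone, the replicate number as a block, a log2 fold change threshold of 1, removal of small RNA genes, and each library left out in turn. Alternatives added after seeing the data were removal of each library's trend in GC content and gene length (known for 14767 genes, 96.5%), thinning of all libraries to 5609350 counts, limma with 1 weight per group, and removal of genes without a poly(A) tail. Figures and library measures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.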

Results

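Gene expression was measured by RNA sequencing in A549, a lung cancer cell line, and MDA-MB-231, a breast cancer cell line, each grown in 2D on a flat surface and in 3D in Matrigel, a basement membrane extract. The series set out to find genes regulated by the extracellular matrix in cancer cells. There were 4 groups of 3 libraries, 12 in all. RNA was taken at about 80% confluence in 2D and on day 4 in 3D. Total expected counts were 17040070, 17717695 and 16453891 in A549 2D and 9873213, 5609327 and 28171901 in A549 3D. They were 21227363, 19624283 and 20518131 in MDA-MB-231 2D and 11624620, 19838477 and 19554124 in MDA-MB-231 3D. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of libraries in a group agreed within sampling noise, with a chi-square per degree of freedom over genes of 2.71 to 163. Levels are given below as mean ± SD of TMM-normalised CPM (n = 3), and log2 fold changes as the estimate ± SE.

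The libraries differed in more than single genes. Mean fragment length was 179.6 ± 5.85 bases in A549 2D and 136.7 ± 3.7 in A549 3D, and 212 ± 4.48 in MDA-MB-231 2D and 184 ± 3.35 in MDA-MB-231 3D. Ribosomal RNA took 0.401% ± 0.0862 of counts in A549 2D and 8.26% ± 7.19 in A549 3D, where the libraries ranged from 3.53% to 16.5%. In MDA-MB-231 it took 1.15% ± 0.0273 in 2D and 4.84% ± 1.43 in 3D. RNase P and RNase MRP RNA, which carry no poly(A) tail, took 1.29% of counts in A549 2D and 5.45% in A549 3D, but 0.000117% and 0.00164% in the MDA-MB-231 groups. Replication-dependent histone genes, whose messengers also lack the tail, took 0.794% in A549 2D and 0.0268% in MDA-MB-231 2D. Between 2D and 3D of each line, and between the lines in 2D, the libraries did not overlap in any of these 4 measures. A two-sided exact permutation test gave p = 0.1 each time, the smallest value that 3 against 3 libraries allow. The biological coefficient of variation was 0.0376 in A549 2D, 0.180 in A549 3D, 0.0538 in MDA-MB-231 2D and 0.0563 in MDA-MB-231 3D. Because the fit shares the estimate of spread over the groups, p-values and SEs may be too small for A549 and too large for MDA-MB-231.

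**Figure D1:**
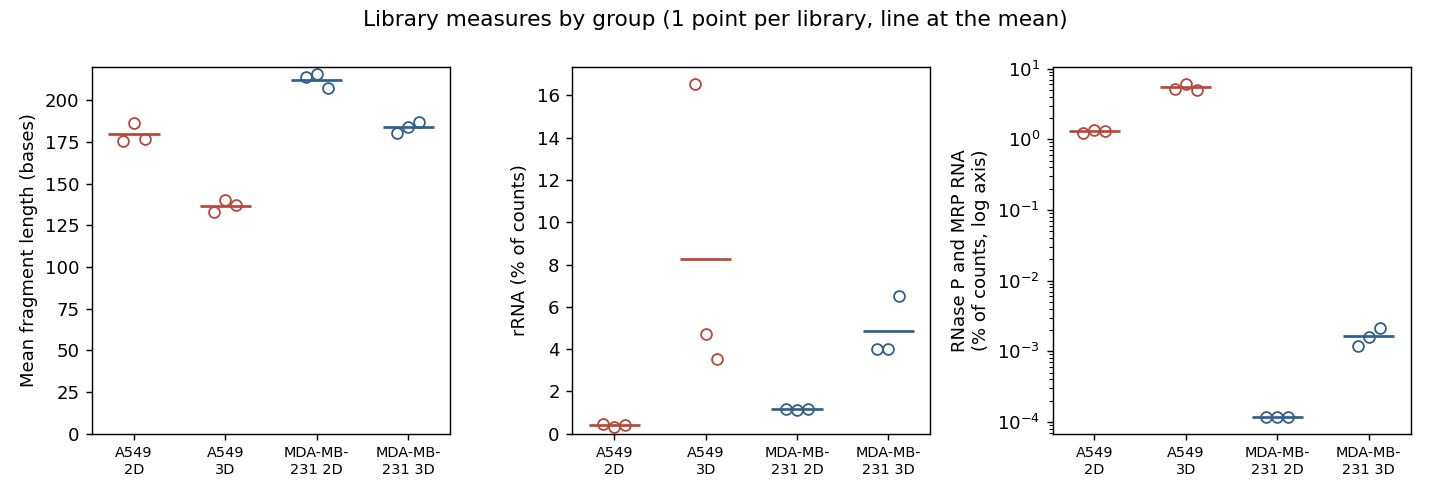
Mean fragment length in bases, ribosomal RNA as a percentage of counts, and RNase P and MRP RNA as a percentage of counts on a log axis, with 1 point per library and a line at the mean of each group of 3. Fragments were shorter in 3D in both lines, and RNase P and MRP RNA took 1.29% of counts in A549 2D against 0.000117% in MDA-MB-231 2D.

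The first comparison asked which genes of A549 differed between Matrigel and flat culture. By camera with its preset correlation, but not with an estimated one, epithelial junction genes, targets of the oxidant defence regulator NRF2 and interferon-stimulated genes were higher in 3D, and genes of cell division were lower. CP, the copper-carrying ferroxidase ceruloplasmin, went from 5.17 ± 0.757 to 1091 ± 348 CPM, a log2 fold change of 7.72 ± 0.26 (edgeR adjusted p = 2.9e-11). CST1, a secreted inhibitor of cysteine proteases, went from 0.184 ± 0.0674 to 87.3 ± 4.24 CPM (8.85 ± 0.18). TXNIP, an inhibitor of thioredoxin, rose by 9.14 ± 0.24 to 45.8 ± 7.29 CPM, and NOX1, a superoxide-producing oxidase, by 8.56 ± 0.25 to 50.2 ± 9.19 CPM. CEACAM6, a cell surface adhesion protein, rose by 7.67 ± 0.21 to 195.5 ± 10.6 CPM. GTF2IP4, a pseudogene reported as uncertain because it shares sequence with its parent gene, was at 0 counts in 2D and at least 799-fold higher in 3D, taking a floor of 3 counts over the group. Its edgeR adjusted p of 0.04699 was 0.0815 to 0.108 when any single A549 library was left out. In MDA-MB-231 this pseudogene was also at 0 counts in 2D, so its absence from 2D was not limited to A549. The MDA-MB-231 3D libraries held 0, 25.6 and 0 CPM, a change that did not pass (edgeR adjusted p = 0.127).

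Among the falls, CCBE1, a secreted protein of lymphatic growth, was 481-fold lower in 3D (2 counts against 1369, 95% counting interval 133 to 3980). GREM1, a secreted antagonist of bone morphogenetic proteins, fell from 122 ± 4.75 to 0.474 ± 0.278 CPM, and CDH4, a cadherin, from 49.9 ± 3.04 to 0.204 ± 0.1901 CPM. The cytokine gene IL11 fell from 45.9 ± 1.18 to 0.293 ± 0.125 CPM, and NPTX1, a secreted pentraxin, from 81.8 ± 2.04 to 0.846 ± 0.4004 CPM. RUNX2, a transcription factor of bone formation, was at 0 counts in 3D and at least 11-fold lower than in 2D. In all, 10056 of 15304 genes tested passed an adjusted p of 0.05, 5228 higher and 4828 lower in 3D, and 3969 of them changed at least 2-fold, 2527 higher and 1442 lower. When the test asked for a change beyond 2-fold, 2469 genes passed.

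Interferon-stimulated genes rose in 37 of 42 measured members in A549 and fell in 2, with a median log2 fold change of 2.43. On the log2(TPM + 1) scale with limma 26 rose and 3 fell, with a median of 0.75. OAS1, an antiviral sensor of double-stranded RNA, rose from 10.5 ± 0.784 to 141 ± 33.9 CPM, and IFITM3, an antiviral membrane protein, from 2.799 ± 0.448 to 17.7 ± 4.298 CPM. Camera gave adjusted p = 3.2e-07, and adjusted p = 0.437 with an estimated correlation. Leukocyte markers moved with these genes, as 4 of 7 rose and 0 fell, with CD14 at 20.4 ± 3.31 and LYZ at 1.101 ± 0.241 CPM in 3D (camera adjusted p = 0.0981). NRF2 targets rose in 26 of 30 members and fell in 3. The glutathione peroxidase gene GPX2 rose from 155 ± 10.6 to 2391 ± 418 CPM and the aldo-keto reductase gene AKR1B10 from 4249 ± 162 to 17550 ± 1501 CPM. Camera gave adjusted p = 1.33e-07 for the NRF2 list, and adjusted p = 0.218 with an estimated correlation.

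Epithelial junction genes rose in 17 of 27 members in A549 and fell in 2. CDH1, which encodes E-cadherin, went from 13.5 ± 0.631 to 65.8 ± 9.78 CPM, and the tight junction gene TJP3 from 0.914 ± 0.169 to 41.1 ± 6.37 CPM (camera adjusted p = 2.91e-04, adjusted p = 0.109 with an estimated correlation). Luminal and basal mammary genes rose in 10 of 14 and fell in 1, among the rises AGR2, a secretory pathway disulfide isomerase, from 118 ± 10.4 to 1455 ± 264.5 CPM (camera adjusted p = 1.4e-04, adjusted p = 0.126 with an estimated correlation). Stem-like cell markers rose in 8 of 13 and fell in 1, with a median of 1.34 that was 0.75 without A549 3D replicate 1, among the rises the surface protein gene CD24 and the efflux pump gene ABCG2 (camera adjusted p = 0.0138, adjusted p = 0.2495 with an estimated correlation). Of 15 alveolar and airway genes 9 rose and 3 fell. The water channel gene AQP3 went from 5.42 ± 0.332 to 240.5 ± 25.98 CPM and the mucin gene MUC5B from 0.655 ± 0.182 to 58.9 ± 11.7 CPM, but camera gave adjusted p = 0.0743 for the list. Its median of 2.23 was 0.51 without A549 3D replicate 1 and 0.05 on the log2(TPM + 1) scale.

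Proliferation genes fell in A549. Of 36 mitosis genes 35 fell and 0 rose, with a median of -1.28, and TOP2A, a DNA topoisomerase of dividing cells, went from 1364 ± 55.4 to 509 ± 35.01 CPM. Camera gave adjusted p = 6.81e-15, and adjusted p = 0.109 with an estimated correlation. Of 38 S-phase genes 37 fell and 0 rose, with a median of -0.95 (camera adjusted p = 9.17e-12, adjusted p = 0.319 with an estimated correlation). Ribosome biogenesis genes and MYC targets fell in 25 of 33 and rose in 2, among the falls NOP58, a core protein of box C/D snoRNA particles, from 161 ± 9.696 to 54.2 ± 7.14 CPM (camera adjusted p = 3.2e-07, adjusted p = 0.2495 with an estimated correlation).

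Targets of the co-activators YAP and TAZ fell in 21 of 28 and rose in 5 in A549 (camera adjusted p = 7.75e-05, adjusted p = 0.0479 with an estimated correlation). Of its members, CYR61, a secreted matrix protein, fell from 37.3 ± 2.17 to 5.25 ± 0.696 CPM, and AJUBA, a LIM domain protein, from 249.9 ± 12.9 to 34.9 ± 2.18 CPM. SRF targets and actin genes fell in 26 of 32 and rose in 6. Tropomyosin TPM1 fell from 1157 ± 49.3 to 172 ± 10.4 CPM, while VIL1, which encodes the microvillar protein villin, rose from 0.817 ± 0.3702 to 50.7 ± 4.02 CPM (camera adjusted p = 5.53e-05, adjusted p = 0.319 with an estimated correlation). Of 50 matrix structural genes 26 fell and 13 rose. The collagen genes COL5A1, COL4A1 and COL7A1 fell by 5.52, 5.10 and 4.63 on the log2 scale, while FN1, which encodes fibronectin, rose from 166 ± 5.78 to 3800 ± 846 CPM. Camera gave adjusted p = 0.02 for this list, and adjusted p = 0.592 with an estimated correlation. Other matrix lists went both ways, with 12 of 29 integrins and matrix receptors higher and 12 lower, 8 of 23 collagen enzymes higher and 8 lower, and 7 of 30 matrix proteases and inhibitors higher and 14 lower (camera adjusted p = 0.829, 0.7202 and 0.201).

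Some further lists were called higher in A549 3D by camera with its preset correlation, but not with an estimated one. Glycolysis genes rose in 17 of 19 and fell in 1, PFKP, while the hexokinase gene HK1 went from 76.1 ± 1.73 to 327 ± 21.9 CPM (camera adjusted p = 6.31e-05, adjusted p = 0.2495 with an estimated correlation). Lysosome and autophagy genes rose in 18 of 27 and fell in 4, with a median of 0.54 that was -0.07 on the log2(TPM + 1) scale (camera adjusted p = 0.01704, adjusted p = 0.541 with an estimated correlation). Without A549 3D replicate 3 its camera adjusted p was 0.0695. Nuclear-encoded respiratory chain genes rose in 26 of 39 and fell in 1, but their median of 0.28 was -0.07 with the trend in GC content and gene length removed and -0.34 on the log2(TPM + 1) scale (camera adjusted p = 9.8e-04, adjusted p = 0.384 with an estimated correlation). Replication-dependent histone genes rose in 14 of 28 and fell in 1, but their median of 0.29 was -0.47 and -0.46 in the same settings, and 0.45 and 0.13 without A549 3D replicates 2 and 3 (camera adjusted p = 0.0137, 0.0782 without A549 3D replicate 3, and adjusted p = 0.592 with an estimated correlation). Fragments were shorter and the share of ribosomal RNA was higher in the same A549 3D libraries.

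The second comparison asked the same of MDA-MB-231. The receptor gene NGFR and HLA-DRB1 and HLA-DQB1 were higher in 3D. By camera with its preset correlation, but not with an estimated one, ribosomal protein, glycolysis, hypoxia-induced and cytokine genes were higher and mitosis genes were lower. NGFR, a receptor of nerve growth factor, went from 0.552 ± 0.178 to 66.5 ± 5.41 CPM, a log2 fold change of 6.90 ± 0.17 (edgeR adjusted p = 3.75e-14). HLA-DRB1 and HLA-DQB1 encode MHC class II chains, which present peptides to helper T cells, and share sequence with related genes, so their values are uncertain. They went from 27.1 ± 1.004 to 613 ± 4.17 CPM and from 0.956 ± 0.126 to 41.4 ± 1.38 CPM. The mucin gene MUC5B went from 0.117 ± 0.0691 to 2.72 ± 0.436 CPM. TERC, the RNA of telomerase, was 83.7-fold higher in 3D (59 counts against 1, 95% counting interval 14.4 to 3360). RPPH1, the RNA of RNase P, went from 0.302 ± 0.285 to 11.7 ± 3.17 CPM, against 3733 ± 316 CPM in A549 2D. In the same libraries the share of counts was 5.15-fold higher in 3D for 7SL and 7SK RNA, 4.21-fold for ribosomal RNA and 2.91-fold for snoRNA and scaRNA. In 2D the share was only 4.8e-05% for 7SL and 7SK RNA and 0.000299% for snoRNA and scaRNA, so these 2 ratios rest on few counts. For replication-dependent histone genes the ratio was 0.677. The rises of TERC and RPPH1 cannot be told apart from such a change in library content.

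Among the falls, PLCXD3, a phospholipase-like gene, was at 0 counts in 3D and at least 108-fold lower than in 2D. IGFL2-AS1, an antisense gene and therefore uncertain, was at 0 counts in 3D and at least 12.2-fold lower. The non-coding RNA LINC02582 fell from 33.4 ± 3.04 to 0.162 ± 0.164 CPM. FOXA1, a transcription factor of luminal cells, was 49.8-fold lower (3 counts against 212, 95% counting interval 16.8 to 244). KISS1, which encodes the precursor of kisspeptin, fell from 28.7 ± 1.05 to 0.687 ± 0.181 CPM, and PCSK6, a proprotein convertase, from 3.11 ± 0.602 to 0.0723 ± 0.08395 CPM. In all, 10351 of 15304 genes passed, 5117 higher and 5234 lower in 3D, and 3630 changed at least 2-fold, 1682 higher and 1948 lower. When the test asked for a change beyond 2-fold, 1738 genes passed.

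Ribosomal protein genes rose in 44 of 47 members in MDA-MB-231 and fell in 0, with a median of 0.75 that was 0.45 with the trend in GC content and gene length removed. RPS19 went from 203 ± 3.16 to 542 ± 32.4 CPM and RPL13 from 245 ± 9.45 to 590.4 ± 10.4 CPM (camera adjusted p = 1.1e-12, adjusted p = 0.197 with an estimated correlation). Glycolysis genes rose in 18 of 19 and fell in 0, among them the aldolase gene ALDOA, from 507.5 ± 29.2 to 1480 ± 45.9 CPM (camera adjusted p = 1.99e-08, adjusted p = 0.197 with an estimated correlation). Hypoxia-induced genes rose in 23 of 32 and fell in 3, among the rises VEGFA, an endothelial growth factor, from 87.4 ± 3.02 to 334 ± 11.8 CPM, and NDRG1, from 61.3 ± 4.06 to 471 ± 16.5 CPM (camera adjusted p = 7.89e-05, adjusted p = 0.293 with an estimated correlation). Respiratory chain genes rose in 28 of 39 and fell in 4, among the rises NDUFS7, a subunit of complex I (camera adjusted p = 3.37e-05, adjusted p = 0.293 with an estimated correlation).

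Heat shock and chaperone genes went both ways in MDA-MB-231, as 7 of 18 rose and 8 fell (camera adjusted p = 0.5001). NF-kB targets, cytokines and chemokines rose in 27 of 39 and fell in 4. SAA1, an acute phase protein, went from 49.4 ± 4.06 to 441 ± 17.1 CPM, and CSF3, a granulocyte growth factor, from 31.3 ± 4.86 to 307 ± 2.31 CPM (camera adjusted p = 3.37e-05, adjusted p = 0.197 with an estimated correlation). ATF4 and amino acid genes rose in 24 of 29 and fell in 2, among the rises ASNS, the enzyme that makes asparagine (camera adjusted p = 7.2e-05, adjusted p = 0.293 with an estimated correlation). Genes of the unfolded protein response rose in 14 of 23 and fell in 3, among the rises SDF2L1, from 2.58 ± 0.701 to 9.97 ± 0.859 CPM (camera adjusted p = 0.00183, adjusted p = 0.293 with an estimated correlation). Immediate-early genes rose in 25 of 35 and fell in 3, with DUSP1, a phosphatase of MAP kinases, among the falls (camera adjusted p = 0.00183, adjusted p = 0.139 with an estimated correlation). NRF2 targets rose in 17 of 30 and fell in 5, among the rises the ferritin gene FTL, from 668 ± 25.5 to 2235 ± 34.7 CPM, and lysosome genes rose in 19 of 27 and fell in 2. Camera gave adjusted p = 0.00591 and 5.97e-04 for these lists, and adjusted p = 0.376 and 0.376 with an estimated correlation.

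Enzymes that process and crosslink collagen rose in 16 of 23 and fell in 5 in MDA-MB-231, among the rises the lysyl oxidase gene LOXL4, from 44.8 ± 0.684 to 226 ± 6.28 CPM (camera adjusted p = 0.00209, adjusted p = 0.293 with an estimated correlation). Matrix structural genes went both ways, with 20 of 50 higher, such as the thrombospondin gene THBS1, and 14 lower, such as the laminin gene LAMA4 (camera adjusted p = 0.4596). TGF-beta induced genes rose in 15 of 24 and fell in 4 (camera adjusted p = 0.0441, adjusted p = 0.293 with an estimated correlation). That call was lost without MDA-MB-231 3D replicate 3 (camera adjusted p = 0.0606) and with the trend in GC content and gene length removed (0.546). Mitosis genes fell in 23 of 36 and rose in 4, among the falls ASPM, a spindle pole protein, from 284 ± 16.1 to 78.6 ± 12.5 CPM (camera adjusted p = 3.26e-04, adjusted p = 0.293 with an estimated correlation). Leukocyte markers rose in 4 of 7 and fell in 0, with CD14 at 17.04 ± 1.47 CPM in 3D, and fibroblast markers fell in 3 of 6 and rose in 1 (camera adjusted p = 0.0596 and 0.324).

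**Figure D2:**
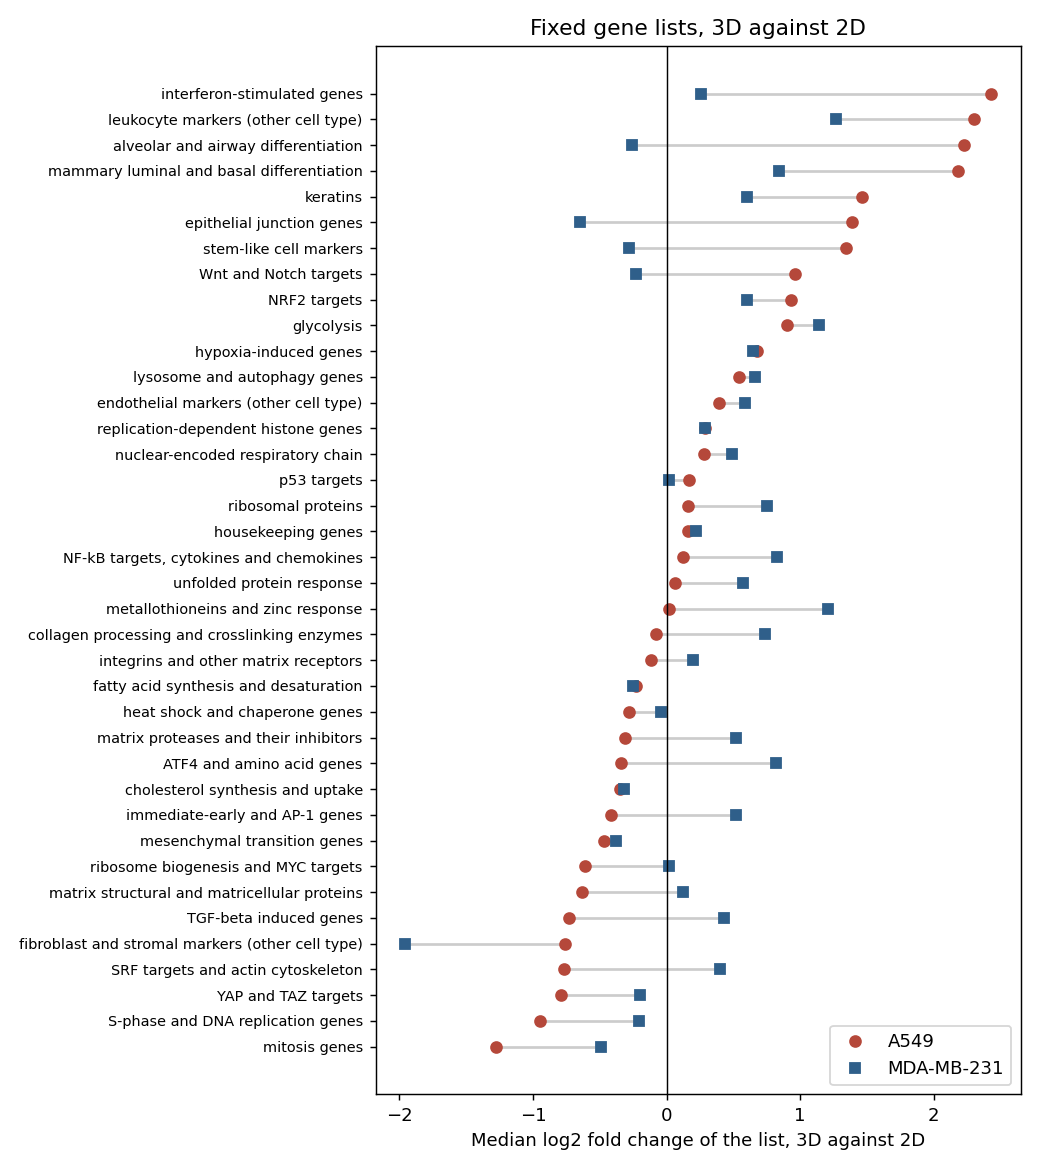
Median log2 fold change, 3D against 2D, of each of the 38 gene lists tested, with circles for A549 and squares for MDA-MB-231. Interferon-stimulated genes had medians of 2.43 and 0.26, the latter -0.1 on the log2(TPM + 1) scale, and mitosis genes had medians of -1.28 and -0.49.

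Adjusted over the list alone, the member counts equalled those over all genes tested for 33 of 38 lists in A549 and 29 of 38 in MDA-MB-231. Among the lists described they differed by 1 member: mitosis genes (1 rose), mammary genes (11 rose) and histone genes (13 rose) in A549, and collagen enzymes (17 rose), lysosome genes (20 rose), heat shock genes (8 rose), immediate-early genes (4 fell) and mitosis genes (5 rose) in MDA-MB-231. Camera with its preset correlation of 0.01 called 15 of the 38 lists in A549 and 13 in MDA-MB-231, and in the other 9 groupings of the same libraries it called 8 to 17 lists in A549 and 10 to 13 in MDA-MB-231. With an estimated correlation it called 1, the YAP and TAZ targets in A549, and 0 in MDA-MB-231. On the log2(TPM + 1) scale with limma, the log2 fold change of each gene was compared with the main analysis. The median shift per gene was -0.54 in A549 and -0.40 in MDA-MB-231. On that scale 2289 genes were higher and 8628 lower in A549, and 2551 higher and 7493 lower in MDA-MB-231. Medians of lists described as higher lay lower there, in A549 at 0.43 for epithelial junction genes (1.39 with TMM scaling), 0.80 for mammary genes (2.18), 0.13 for stem-like cell markers (1.34), 0.34 for NRF2 targets (0.93) and 0.33 for glycolysis (0.90). In MDA-MB-231 they were 0.28 for ribosomal proteins (0.75 with TMM scaling), 0.06 for the respiratory chain (0.49), 0.06 for NRF2 targets (0.60), 0.07 for immediate-early genes (0.52), 0.01 for TGF-beta induced genes (0.43) and 0.4 for ATF4 and amino acid genes (0.82). They were 0.4 for NF-kB targets (0.83), 0.24 for lysosome genes (0.66), 0.64 for glycolysis (1.14), 0.31 for collagen enzymes (0.74), 0.19 for hypoxia-induced genes (0.65) and 0.15 for the unfolded protein response (0.57). With the trend in GC content and gene length removed, the median shift per gene was -0.11 in A549 and 0 in MDA-MB-231. With it removed, 4438 genes were higher and 5961 lower in A549, and 4927 higher and 3650 lower in MDA-MB-231. In that setting MDA-MB-231 medians were 0.47 for ATF4 and amino acid genes, 0.51 for NF-kB targets, 0.25 for the respiratory chain, 0.36 for lysosome genes, 0.38 for NRF2 targets and -0.26 for mitosis genes, which had -0.49 with the trend kept and -0.9 on the log2(TPM + 1) scale. The changes given here are relative to the TMM scaling.

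A further comparison tested whether the 3D change differed between the lines. NOX1, PLCXD3 and IGFL2-AS1 rose in A549 and were at 0 counts in MDA-MB-231 3D, so that with a floor of 3 counts over that group the change was at least 8.97, 7.67 and 7.19 more positive in A549 on the log2 scale. CP rose in A549 and had 12 counts in MDA-MB-231 2D and 2 in 3D, a difference of 9.7 from the count sums (95% counting interval 7.53 to 12.9). LINC02582 rose in A549 and fell in MDA-MB-231, a difference of 9.88 ± 0.58. COL5A1 fell in A549 and rose in MDA-MB-231 from 58.5 ± 4.196 to 127 ± 4.13 CPM, a difference of -6.65 ± 0.17. CCBE1 and CDH4 fell further in A549. The difference was -8.46 from the count sums for CCBE1 (95% counting interval -11.51 to -6.61) and -6.65 ± 0.28 for CDH4. IL11 fell in A549 and rose in MDA-MB-231 from 85.3 ± 1.68 to 98.98 ± 3.91 CPM (-7.17 ± 0.19). RUNX2 fell to 0 counts in A549 and was at 32.1 ± 1.402 and 36.96 ± 1.31 CPM in MDA-MB-231 2D and 3D. With the floor its change was at least 3.67 more negative in A549, a difference that did not pass on the log2(TPM + 1) scale (limma adjusted p = 0.414). In all, 8587 of 15304 genes passed, 4502 with a more positive change in A549 and 4085 with a more negative one. With the trend in GC content and gene length removed the split was 3152 to 5385.

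Among lists, the change of interferon-stimulated genes was more positive in A549 for 33 of 42 members and more negative for 0, and that of epithelial junction genes for 20 of 27 and 1. The change was more negative in A549 for 22 of 32 SRF targets and more positive for 7. It was more negative for 36 of 47 ribosomal protein genes and more positive for 1, and for 24 and 2 of 29 ATF4 and amino acid genes. In this order camera gave adjusted p = 6.4e-07, 1.14e-05, 1.14e-05, 3.6e-10 and 8.86e-07, and adjusted p = 0.416, 0.0775, 0.245, 0.209 and 0.209 with an estimated correlation. Of the 38 lists, 18 passed camera with its preset correlation and 0 with an estimated one.

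The next comparison asked which genes changed the same way in both lines. CD14, a receptor of bacterial lipopolysaccharide, rose by 3.31 ± 0.15 in A549 and 3.22 ± 0.14 in MDA-MB-231 on the log2 scale. HLA-DMB, which helps load peptides on MHC class II, rose from 1.88 ± 0.196 to 123 ± 24.1 CPM in A549 and from 6.295 ± 0.372 to 45.3 ± 4.31 CPM in MDA-MB-231. MUC5B and RPPH1 rose in both lines. The share of 7SL and 7SK RNA was also higher in 3D, 5.43-fold in A549 and 5.15-fold in MDA-MB-231, so the rise of RPPH1 may reflect library content. In MDA-MB-231 2D that share was only 4.8e-05% of counts, so the ratio of that line rests on few counts. IFI27, an interferon-stimulated gene, rose in both, but its A549 3D libraries held 2.76, 1.37 and 19.3 CPM. TAGLN, an actin-binding protein of contractile cells, fell from 58.6 ± 3.25 to 1.43 ± 0.615 CPM in A549 and from 28.4 ± 0.517 to 4.87 ± 0.865 CPM in MDA-MB-231. PEAR1, GFRA1 and LTB4R fell by 3.74, 2.45 and 2.26 in A549 and fell by 2.57, 3.61 and 3.12 in MDA-MB-231 on the log2 scale. KRT7-AS, antisense to a keratin gene and therefore uncertain, fell by 3.13 in A549 and fell by 2.23 in MDA-MB-231.

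In all, 4814 genes passed in both lines in the same direction, 2344 higher and 2470 lower in 3D, where independent lists of the same sizes would share 1748 and 1651.2. Opposite directions were taken by 2182 genes, against 3402.3 for independent lists. Among changes of at least 2-fold, 955 genes shared a direction against 461.3, and 314 did not against 480.1. No library is shared between the comparisons, but fragments were shorter and ribosomal RNA took a higher share in 3D in both lines. Genes higher in A549 3D moved up as a set in MDA-MB-231 (limma fry adjusted p = 9.24e-07 over 4 such sets), with a median of 0.28. Those lower in A549 3D moved down (limma fry adjusted p = 5.39e-07), with a median of -0.33. Across genes, which are not independent replicates, the log2 fold changes of the lines had Pearson's r = 0.16 and Spearman's rho = 0.254. The shared count was 350 when each test asked for a change beyond 2-fold, 2932 with all libraries thinned to the shallowest, 4048 with the trend in GC content and gene length removed, and 5725 on the log2(TPM + 1) scale, 625 of them higher.

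**Figure D3:**
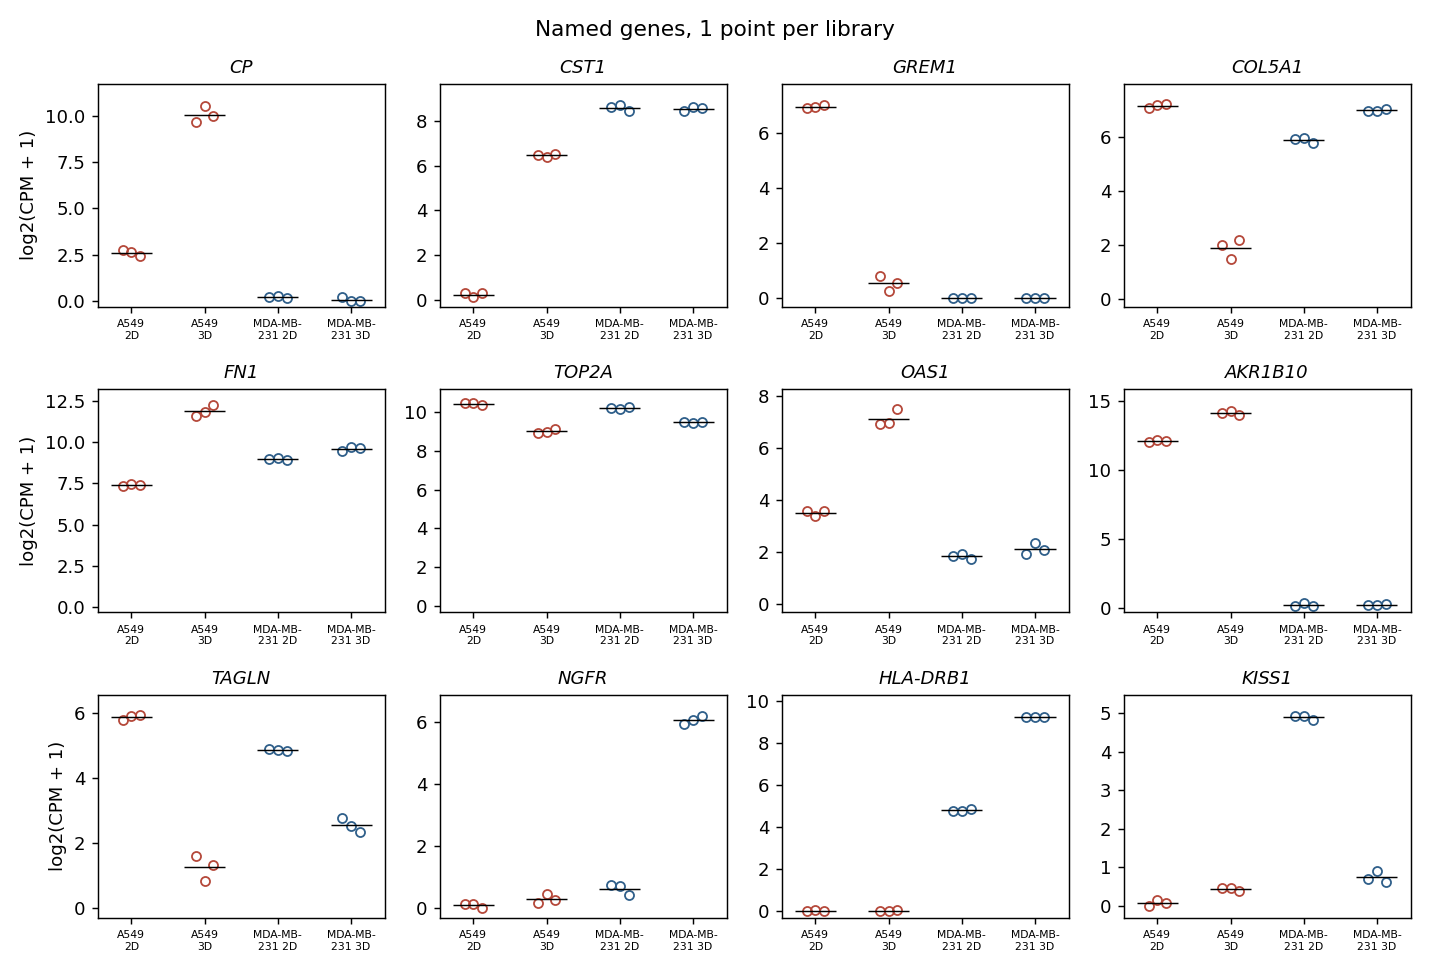
Level of 12 named genes on the log2(CPM + 1) scale, with 1 point per library and a line at the mean of each group of 3 (A549 and MDA-MB-231 in 2D and 3D). The mean of COL5A1 went from 144 to 2.77 CPM in A549 and from 58.5 to 127 CPM in MDA-MB-231.

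The lines were also compared within each culture. In 2D, ALDH1A1, a retinaldehyde dehydrogenase, reached 8525 ± 100.1 CPM in A549 and 1 count in MDA-MB-231 (587000-fold, 95% counting interval 105000 to 23200000). UCHL1, a neuronal ubiquitin hydrolase, CPLX2, a regulator of vesicle fusion, and TALAM1, an antisense RNA and therefore uncertain, were at least 11800-fold, 9720-fold and 12700-fold higher in A549, with 0 counts in MDA-MB-231. The collagenase gene MMP1, the adhesion receptor gene ADGRF5, the collagen gene COL8A1 and the cystatin gene CST4 were at least 27300-fold, 9250-fold, 2160-fold and 1100-fold higher in MDA-MB-231, with 0 counts in A549. In 2D 12489 genes differed, 6552 higher and 5937 lower in A549, and in 3D 12687 differed, 6706 higher and 5981 lower. Asking for a difference beyond 2-fold left 5887 genes in 2D and 6718 in 3D. On the log2(TPM + 1) scale the median shift per gene from the main analysis was -0.77 in 2D and -0.91 in 3D. On that scale 3175 genes were higher and 9490 lower in A549 in 2D, and 3547 higher and 9561 lower in 3D. These comparisons also carry the difference in RNase P, RNase MRP and histone RNA between the lines' libraries.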

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

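Tests chosen only after the result was seen were those of poly(A) selection, of leukocytes in both lines, of GC content and gene length, of 1 library of MDA-MB-231 in 3D, and the regroupings of the shared genes and of the gene lists.

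The change from 2D to 3D differed between the lines, by the test of the difference itself, for 8587 genes. Fitted differences, A549 minus MDA-MB-231 on the log2 scale, were 12.04 for NOX1, 10.88 for PLCXD3, 10.12 for IGFL2-AS1, 9.88 for LINC02582 and 9.62 for CP. They were -8.28 for CCBE1, -7.17 for IL11, -7.13 for RUNX2, -6.65 for CDH4 and -6.65 for COL5A1. Those of NOX1, PLCXD3, IGFL2-AS1 and RUNX2 rest on a group at 0 counts and depend on the prior count. With a floor of 3 counts over that group, the change was at least 8.97, 7.67 and 7.19 more positive and at least 3.67 more negative in A549. Those of CP and CCBE1 rest on a group with 2 counts (95% counting intervals 7.53 to 12.9 and -11.51 to -6.61). By camera with its preset correlation 18 of 38 lists differed, and with an estimated correlation 0 did. Median differences were 2.51 for alveolar and airway genes, 2.06 for interferon-stimulated genes, 1.78 for mammary genes, 1.57 for epithelial junction genes and 1 for stem-like cell markers. They were -1.4 for SRF targets, -1.02 for matrix structural genes, -0.95 for ATF4 genes, -0.9 for S-phase genes, -0.87 for collagen enzymes, -0.85 for ribosome biogenesis genes and -0.81 for immediate-early genes. They were -0.65 for mitosis genes, -0.61 for ribosomal proteins, -0.49 for the unfolded protein response, -0.41 for matrix proteases, -0.36 for YAP and TAZ targets and -0.3 for glycolysis. On the log2(TPM + 1) scale the median difference was 0.92 for alveolar and airway genes, 1.04 for interferon-stimulated genes, 0.8 for mammary genes, 0.69 for epithelial junction genes and -0.48 for glycolysis. With the trend in GC content and gene length removed it was 1.14 for mammary genes, 0.48 for stem-like cell markers, -1 for mitosis genes, -0.82 for YAP and TAZ targets and -0.14 for glycolysis. Without A549 3D replicate 1 it was 2.12 for alveolar and airway genes, and without A549 3D replicate 3 -0.62 for matrix proteases.

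RNase P and MRP RNA, snoRNA and replication-dependent histone genes, which lack a poly(A) tail, were far lower in the MDA-MB-231 libraries than in A549. Ribosomal RNA, which also lacks it, took 1.15% of counts against 0.401% in 2D. In 3D it took 4.84% against 8.26%, where the libraries overlapped. Since the labels name its removal for all libraries, its share cannot decide on poly(A) selection. Mitochondrial ribosomal RNA took 0.359% of counts in MDA-MB-231 2D and 0.0117% in A549 2D. A loss of short messengers would have removed ribosomal protein messengers along with histone messengers, but their median A549 minus MDA-MB-231 difference in 2D was 0.54. That value does not cover RNase P and MRP RNA or snoRNA, so a loss limited to these was not tested. Fewer dividing cells would have lowered S-phase genes too, but their median difference was 0.26. How far these genes would have fallen is not known. Replication-dependent histone genes stood 9.49 above histone genes with a poly(A) tail in that difference, which is consistent with selection for poly(A) RNA in the MDA-MB-231 libraries, although the labels name removal of ribosomal RNA for all libraries. If the libraries were of different types, type and cell line would coincide, and part of each difference between the lines may come from the library. No other biological explanation was tested.

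Interferon-stimulated genes were higher in A549 3D. The tables argue against 1 library as the whole source, since the lowest list median without 1 A549 3D library was 1.78, and against GC content and gene length, since the median was 2.15 with that trend removed. On the log2(TPM + 1) scale it was 0.75. Leukocytes would bring PTPRC, which was at 0.01315 CPM in A549 3D, although CD14, CD68, LYZ and ITGAX rose. Matrigel culture itself and reads from mouse RNA in the matrix stay open, and neither was tested.

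MHC class II genes, a list written after the data were examined, were higher in MDA-MB-231 3D. The tables argue against leukocytes, since PTPRC was at 0.5235 CPM in 2D and 0.06614 CPM in 3D, although CD14, CD68, CSF1R and LYZ rose, and against reads shared between paralogous HLA genes, since CD74 and CIITA, which have no close copy, had a mean log2 fold change of 2.78. They also argue against 1 library, since the lowest median without 1 MDA-MB-231 3D library was 3.82. Matrigel culture itself and reads from mouse RNA in the matrix stay open, and neither was tested. The differences in fragment length, ribosomal RNA share and harvest point between 2D and 3D coincide with culture in this line as well, and stay open too.

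For other groupings of the same libraries, 10 splits are too few for a share under 0.05. A549 culture groups gave 10056 genes and the highest other split 0, with 1 of 10 splits as high, the real one. MDA-MB-231 gave 10351 and the highest other 1 (1 of 10), the lines in 2D 12489 and the highest other 0 (1 of 10), and the lines in 3D 12687 and the highest other 0 (1 of 10). For gene lists, 4 of 10 splits called as many as the 15 in A549, with 17 the highest other, and 3 of 10 called as many as the 13 in MDA-MB-231, with 13 the highest other. The other splits mix 2D and 3D libraries and may keep part of the culture change, so they cannot decide whether the list calls are chance. For the difference between the lines 1 of 100 drawn splits, the real one, reached 8587. The highest other, which kept the culture groups of 1 line, called 5407. Each other drawn split mixed 2D and 3D libraries in at least 1 line, which puts the culture change into the spread and lowers the count. These splits therefore cannot decide whether the difference between the lines is chance. For genes changed the same way in both lines 1 of 100 reached 4814, and the highest other called 1. No other split of 1 line called more than 1 gene, which limits the shared count of each other split, so these splits say nothing on whether the agreement between the lines is chance.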

How the results depend on the processing

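Alternatives chosen only after the data were seen were the removal of the trend in GC content and gene length, thinning to the shallowest library, limma with 1 weight per group and removal of genes without a poly(A) tail. Counts by direction moved by more than 1.5 times on the log2(TPM + 1) scale. Genes higher in 3D numbered 2289 against 5228 in A549 and 2551 against 5117 in MDA-MB-231. Genes higher in A549 numbered 3175 against 6552 in 2D and 3547 against 6706 in 3D. Totals over both directions stayed within 1.5 times the reported ones except as follows, where the cause was not tested unless given. With a log2 fold change threshold of 1, which asks for more by construction, 2469 genes passed in A549, 1738 in MDA-MB-231, 2144 for the difference between the lines, 5887 between the lines in 2D, 6718 in 3D and 350 in both lines. Thinned to the shallowest library, so with fewer counts, 5659 passed for the difference and 2932 in both lines. Camera with an estimated correlation called 1 list in A549 and 0 in MDA-MB-231, and fry called 34 and 33. With the trend in GC content and gene length removed, the median of the respiratory chain in A549 was -0.067 (camera adjusted p = 0.939) and that of replication-dependent histone genes in A549 was -0.468 (0.0167). Leaving out 1 library at a time gave 9313 to 10645 genes in A549, 9537 to 10952 in MDA-MB-231, 7954 to 8975 for the difference, 12066 to 13093 and 12453 to 12999 between the lines in 2D and 3D, 4330 to 5536 in both lines, and 16 to 17 and 13 to 14 lists in A549 and MDA-MB-231. The replicate numbers did not pair the libraries. Deviations of libraries with the same number in a line had correlations from -0.075 to 0.068, and all pairs of a 2D and a 3D library from -0.085 to 0.118. With the replicate number as a block, 9700, 10109, 8390, 12325, 12543 and 4554 genes passed in the same order, and 17 and 15 lists. Of 170 named gene values, the direction held in all settings run, and the calls lost were 20 with the threshold of 1, 5 on the log2(TPM + 1) scale, 2 with the GC and length trend removed, 1 without a filter, 1 with thinning and 6 of the values with 1 library left out, all 6 of GTF2IP4. Depth limits genes near the floor most in A549 3D, where the shallowest library held 5609327 counts. Spread was also largest in A549 3D, while the main fit shares its estimate over the groups. With the 6 libraries of a line fitted alone, 8752 genes passed in A549 and 10972 in MDA-MB-231, against 10056 and 10351 in the main fit. With limma and 1 weight per group, 8972 and 11307 passed.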

Other observations

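Lists of MHC class I, MHC class II and interferon genes were written, and gene families chosen, only after the data were examined.

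In MDA-MB-231, 12 of 12 MHC class II genes rose in 3D, with a median log2 fold change of 3.85. HLA-DRA went from 56.3 ± 0.745 to 621 ± 12.7 CPM, CD74, the invariant chain, from 155.5 ± 22.3 to 1273 ± 74.4 CPM, and CIITA, the co-activator of class II genes, from 7.88 ± 0.593 to 45.1 ± 3.32 CPM. In A549, 2 of 12 rose, HLA-DMA and HLA-DMB, and HLA-DRA had 0 counts in all libraries. The rise was not limited to class II. Of 12 genes of MHC class I presentation 11 rose and 0 fell in MDA-MB-231, with a median of 1.29. In A549 8 of them rose and 1 fell, with a median of 0.71. IFNB1 had 1 count in A549 3D and 0 in the other groups, and IFNG had 0 in each group. Of 5 interferon receptor genes 3 rose and 0 fell in A549, and 1 rose and 4 fell in MDA-MB-231.

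Among families of at least 8 tested genes that share a symbol stem, chosen because nearly all members moved the same way, all 10 AKR genes, which encode aldo-keto reductases, rose in A549 3D, with a median log2 fold change of 1.43. UGT genes, which encode glucuronosyltransferases and share sequence, rose in 9 of 10, with a median of 3.19. MCM genes fell in 11 of 11, with a median of -0.73, and TUBB tubulin genes fell in 7 of 8 and rose in 1.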
